A study of Homo sapiens with 2 samples.

How the data were processed

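Total RNA from K562 cells, a human line derived from a chronic myeloid leukaemia in blast crisis, was hybridised to Affymetrix expression arrays. Cells carried either the empty retroviral vector pMSCV or a retrovirus for PML4, and both were selected in G418 for 3 weeks, per the labels. Each group holds 1 array. Biotin-labelled cRNA was made from 6 µg of total RNA, per the labels.

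The deposited values are MAS5 signal intensities on a linear scale. MAS5 is named, without a version, per the submitters' processing notes. MAS5 summarises the perfect-match and mismatch probes of a probe set into 1 signal and scales each array to a common target. In the deposited intensities, the mean without the lowest and highest 2% of probe sets was 499.9 on the control array and 500.0 on the PML4 array. Software version and settings are not given in the sources used here, and detection calls were not used here. The table holds 54675 probe sets, of which 62 are control probe sets and 54613 are human. Signals ran from 0.1 to 53703.3 on the control array and from 0.1 to 47622.1 on the PML4 array.

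Gene names came from GEO's annotation of the array. It gave 1 gene for 41097 probe sets and several genes for 1801, and 11721 human probe sets had no entry in the table used. Genes were named only from probe sets with 1 gene. Of these, 41043 matched a current gene through the Entrez identifier, and none needed another symbol. The annotation names no genome build, so no coordinates are given. Which genes neighbour each other was taken from the RefSeq annotation of GRCh38.p14.

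Everything from here on was computed for this text. The 2 arrays were used as scaled by the authors, with no further normalization. The floor was the median signal of all human probe sets over both arrays, 72.4. A probe set counted as measured when it lay above the floor on at least 1 array, which held for 29370 probe sets. Signals under the floor were raised to it before taking log2, so a difference with 1 side at the floor is a lower bound. The difference is log2 PML4 minus log2 control vector. A gene took its measured probe set with the highest mean log2 signal, which left 12541 genes, 11051 of them above the floor on both arrays. A gene was called higher or lower when it differed by at least 2-fold.

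With 1 array per group there is no replicate error, so the groups were not compared by a statistical test and no p-value or standard error is given. Lists and runs of genes were set against random draws of genes, which says nothing of the error between cultures. The spread taken for genes was that between probe sets of 1 gene. Control transcripts read on both arrays, given under Results, are a separate check of the arrays. Over 16239 pairs of probe sets in 5453 genes, their differences lay a median of 0.29 apart on the log2 scale. The SD of the signed gaps, scaled down to that of a single probe set, was 0.35. This covers neither the error between arrays nor that between cultures, and nothing in the labels lets these arrays show the spread between cultures. The median was used as the spread when a value was set against its alternatives. The low end of the scale is the least precise, since it lies near background. The number of arrays limits the precision of every value here.

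36 gene lists were written before the data were examined, as were the settings, the alternatives and the naming rule. They hold 992 different genes, of which 888 had a probe set of their own and 762 were measured. For each list the median difference was set against 10000 random lists of the same size, matched on mean signal in 20 bins. A list was said to stand apart when its median lay outside the central 95% of those lists, which chance gives for about 1.8 of 36 lists. This describes these 2 arrays and is not a p-value, because genes of a list move together between any pair of cultures.

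The genes named are those of a fixed rule. It takes every probe set of PML. It takes the 10 largest differences in each direction among genes called, above the floor on both arrays, at or above the 75th percentile of mean signal and with all measured probe sets differing the same way. It takes list members that were called, at most 4 per list, and 10 fixed erythroid and megakaryocyte genes. Last, it takes the 5 largest bounds in each direction for genes above 2 times the floor on one array and at the floor on the other. The 3 members of highest mean signal of each list that stood apart were added after the values were seen, as were the other genes described as such.

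Alternatives were floors at the 25th and 75th percentile, no floor with a pseudocount of 32, centring on the median gene, quantile normalization, loess centring with a span of 0.4, the mean over a gene's probe sets, leaving out probe sets ending in _x_at or _s_at, calls at 1.5-fold and 3-fold, and 10 bins. Centring shifts a list and its random lists alike, so it cannot change the side of a list. Matching in 10 bins changes the random range but not the list's median. Counts of alternatives for lists include centring. Work was done in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1. The scripts were tested on simulated data for this comparison over 12541 genes. At a simulated fold of 2, 42% of 50 changed genes were called, and at a fold of 4, 98% of 50. A fold of 2 is the size of a call itself, so there the noise alone decides on which side a gene falls. The changed genes were drawn only from those above the median of mean signal, and the fold was added after the floor. These shares therefore do not cover dimmer genes or changes that the floor cuts short. Of the genes left unchanged, 4.32% were called, since the noise was resampled from the real differences, which hold any real effect too. Of 200 random lists of 25 genes, 3.5% stood apart, and 98% of 100 lists shifted by 0.3 did. The 3.5% is small by construction, because lists drawn at random were set against other random draws. It says nothing of lists whose genes move together.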

Results

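Gene expression was measured on 2 arrays, 1 from K562 cells with the empty vector pMSCV and 1 from K562 cells overexpressing PML4. PML4 is an isoform of the promyelocytic leukaemia protein, the scaffold of PML nuclear bodies. K562 cells carry the BCR-ABL fusion and express erythroid and megakaryocyte genes. The design asks which transcripts differ in level when PML4 is overexpressed. No value has a replicate, so every difference is that between these 2 arrays. On the control array 51.9% of human probe sets lay above the floor of 72.4, and on the PML4 array 48.1%. Across the 25219 probe sets above the floor on both arrays, log2 signals correlated with a Pearson r of 0.97 and a Spearman rho of 0.97, a relation across probe sets, which are not independent replicates.

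RNA quality controls of GAPDH and ACTB and the brighter hybridisation controls were close on the arrays. The 3' to 5' signal ratio of GAPDH, the glycolytic enzyme used as an integrity control, was 1.55 on the control array and 1.53 on the PML4 array. That of ACTB, beta-actin, was 2.94 and 2.80, and that of 18S rRNA was 2.19 and 1.14. The 12 probe sets for the brighter spiked hybridisation transcripts had a median PML4 to control ratio of 0.943, between 0.892 and 1.06. The bioB transcript, the dimmest of the hybridisation controls, was left out of the 12, and the ratios of its probe sets ran from 0.736 to 1.56. Ratios of the probe sets for the bacterial control transcripts dap, lys, phe and thr ran from 0.441 to 1.72, both ends at signals near the floor. The brightest of these, both for dap, had ratios of 0.771 and 1.07. Dim control transcripts thus differed between the arrays by sizes near that of a call.

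PML itself was read by 10 probe sets, and they did not move together. The probe set 211013_x_at, which has the highest mean log2 signal of them and stands for the gene, was at 216.3 on the control array and 1386.8 on the PML4 array, a 6.41-fold higher signal. Another, 210362_x_at, was 7.12-fold higher, at 98.1 on the control array and 698.5 on the PML4 array. In contrast, 206503_x_at was at 927.2 on the control array and 156.5 on the PML4 array, which is 5.92-fold lower. The probe set 211012_s_at was 1.99-fold higher, 211014_s_at and 235508_at were 1.17-fold and 1.18-fold higher, and 209640_at was 1.51-fold lower. The probe sets 211588_s_at and 239582_at were above the floor on the control array only, at 98 and 94.6, and 211589_at was under the floor on both arrays. Averaged over all measured probe sets the PML difference was 0.33 on the log2 scale. When probe sets ending in _x_at or _s_at were left out, 235508_at alone stood for the gene, at 0.23. The other measured ones without these endings, 209640_at and 239582_at, were at -0.59 and -0.39, the latter a bound. Both the size and the direction therefore depend on which probe sets are read. The positions of the probes relative to the transduced cDNA were not used here.

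**Figure D1:**
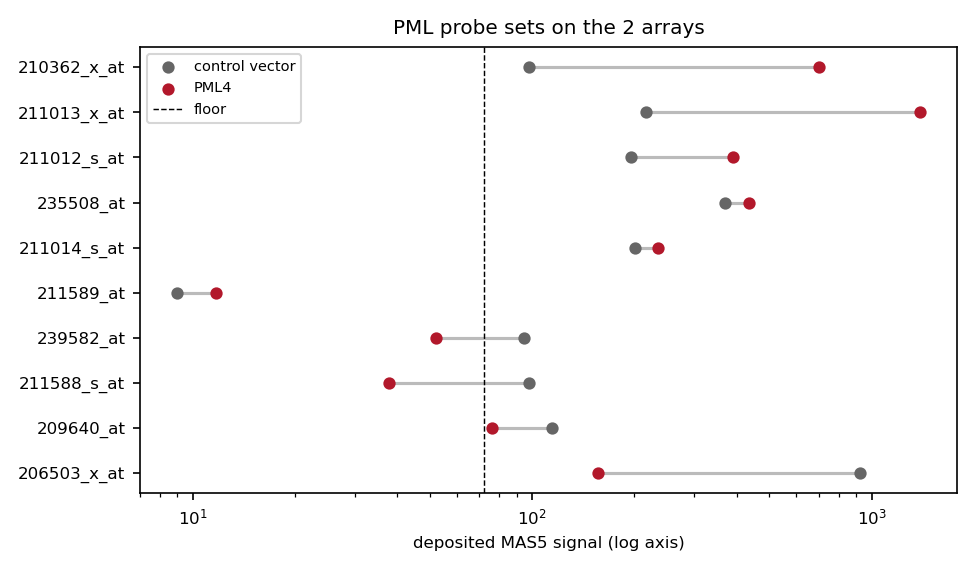
Deposited MAS5 signal (log axis) of the 10 PML probe sets on the control vector array (grey) and the PML4 array (red), 1 array each, ordered by their difference, with the floor of 72.4 as a dashed line. 210362_x_at and 211013_x_at were over 6 times brighter with PML4, whereas 206503_x_at was at 927.2 and 156.5.

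Other components of PML nuclear bodies were not called. Of 23 measured genes of that list, PML was the only one that differed by at least 2-fold, and SP100, a resident protein of these bodies, was at 1238.3 and 1239.0. The list's median difference was 0.02 on the log2 scale, inside the central 95% of matched random lists, which ran from -0.14 to 0.19.

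Across all genes, 154 of 12541 were at least 2-fold higher with PML4 and 402 were at least 2-fold lower. Of these, 35 of the higher and 117 of the lower genes were bounds with 1 side at the floor. Calls were concentrated at low signal: the 3136 dimmest genes held 71 of the higher and 227 of the lower calls, and the 3135 brightest held 16 and 22. Among called genes with several measured probe sets, all of these differed in the same direction for 37 of 53 higher and 130 of 151 lower genes. Calls made up 4.43% of genes. The 4.32% called in simulated data with no change gives no rate of false calls, because its noise was drawn from these same differences. Among genes at or above the 75th percentile of signal whose probe sets all differed one way, the largest differences upward were led by HBZ, the embryonic zeta-globin, at 1401.4 and 5465.5, a 3.90-fold difference. PRF1, which encodes the pore-forming protein perforin, was 3.36-fold higher, at 3459.0 and 11617.0. CAVIN1, a component of caveolae, was 2.53-fold higher, and CITED2, a transcriptional co-regulator, 2.48-fold. KRT19, a keratin gene, was 2.27-fold and CTSC, the protease cathepsin C, 2.26-fold higher. NICOL1, LYSMD2, IMMP1L and MPC2, the last a subunit of the mitochondrial pyruvate carrier, were between 2.02-fold and 2.17-fold higher. After quantile normalization and after loess centring LYSMD2, IMMP1L and MPC2 fell just under the size of a call, at log2 differences of 0.976 to 0.997. The log2 difference of IMMP1L was 0.44 without probe sets ending in _x_at or _s_at.

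Among genes chosen in the same way, the largest differences downward were led by DDIT4, an inhibitor of mTORC1 signalling, at 11645.4 on the control array and 3236.0 on the PML4 array, a 3.60-fold difference. DDIT3, the stress transcription factor CHOP, was 3.19-fold lower. VEGFA, the angiogenic growth factor, was 2.84-fold lower in all 4 of its probe sets by direction. TRIB3, a pseudokinase induced by stress, was 2.77-fold lower, SLC7A11, the cystine transporter, 2.54-fold, and ASNS, asparagine synthetase, 2.31-fold. TUBE1, TM6SF1, SEL1L3 and FAM83A were between 2.32-fold and 2.51-fold lower.

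Some genes were at the floor on one array, so their difference is a bound. SLC18A2, a vesicular monoamine transporter, was at 32.9 on the control array and 608.6 on the PML4 array, at least 8.41-fold higher. TRDV3, a T cell receptor delta segment, was at least 6.79-fold higher, LOC105371763 at least 3.59-fold, TMEM45A at least 3.02-fold and MTA2 at least 2.84-fold. The other TRDV3 probe set was under the floor on both arrays. CXCL8, the chemokine interleukin-8, was at 460.0 on the control array and 58.0 on the PML4 array, at least 6.35-fold lower. MAP4K3-DT was at least 5.03-fold lower, MUC4, at 361.7 and 71.9, by a like size, TMEM178A at least 4.49-fold and DSCR10 at least 4.47-fold. With the mean of its probe sets MUC4 had a log2 difference of -0.88, under the size of a call.

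The split of calls depended on scaling. The median probe set was at 80.6 on the control array and 64 on the PML4 array. Quantile normalization gave 196 higher and 281 lower genes, and loess centring gave 201 and 265. The share of calls that were higher was 27.7% as deposited, 41.1% after quantile normalization and 43.1% after loess centring. It was 44.2% with the floor at the 75th percentile, which left 50 higher and 63 lower genes.

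**Figure D2:**
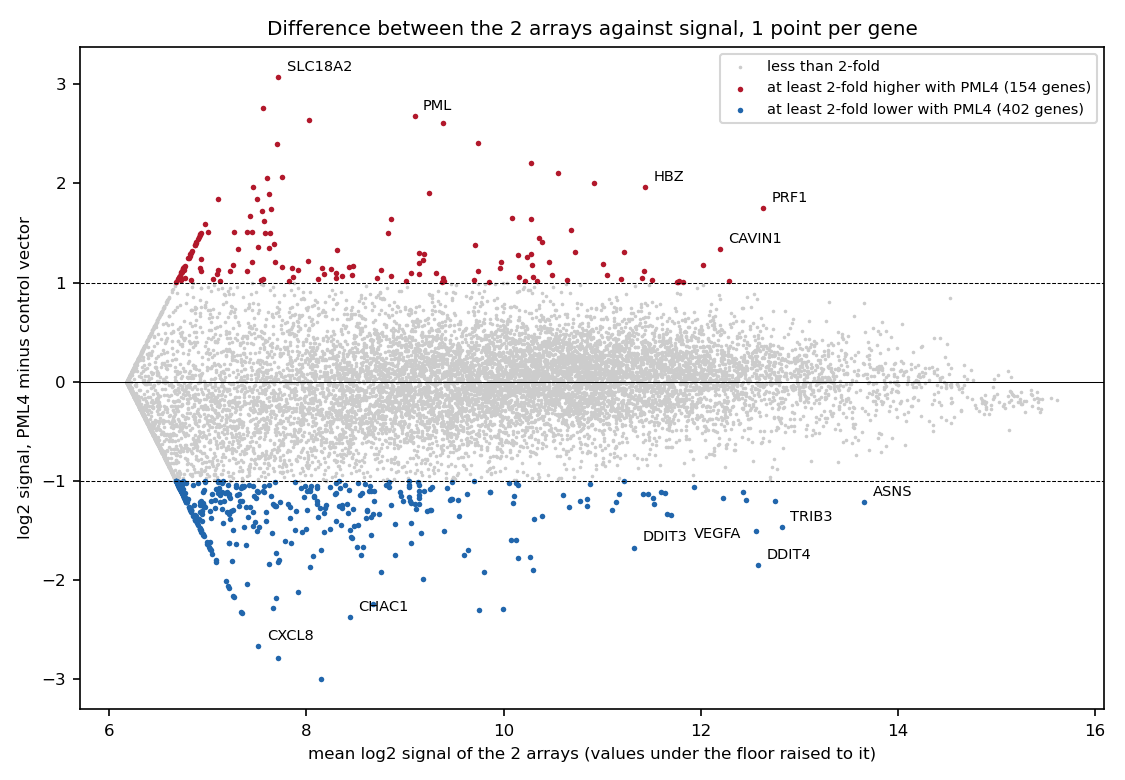
Log2 signal with PML4 minus that with the control vector (vertical axis) against the mean log2 signal of the 2 arrays (horizontal axis) for the 12541 measured genes, 1 array per group, with dashed lines at 2-fold. The 154 higher genes are red and the 402 lower genes blue, and lower genes outnumber higher ones mostly at low signal.

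Genes of the integrated stress response and of amino acid supply were lower with PML4 as a group. All 28 measured members had a lower signal as deposited, 10 of them by at least 2-fold. The largest differences were in CHAC1, a glutathione-degrading enzyme, at 5.19-fold lower, ALDH1L2, a mitochondrial folate enzyme, at 4.34-fold, DDIT4 at 3.60-fold and the transcription factor ATF5 at 3.42-fold. With the floor at the 75th percentile the log2 differences of CHAC1 and ALDH1L2 were -0.77 and -0.11, under the size of a call. The 3 brightest members were below 2-fold: GARS1 was at 21752.3 and 17091.9, MTHFD2 at 19214.2 and 12939.4, and SLC38A2 at 16852.8 and 14248.8, on the control and PML4 arrays. The list's median difference was -0.76 on the log2 scale, below all 10000 matched random lists, whose central 95% ran from -0.11 to 0.15. It stayed below that range under all 9 alternatives, between -0.79 and -0.66, though centring could not change its side.

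**Figure D3:**
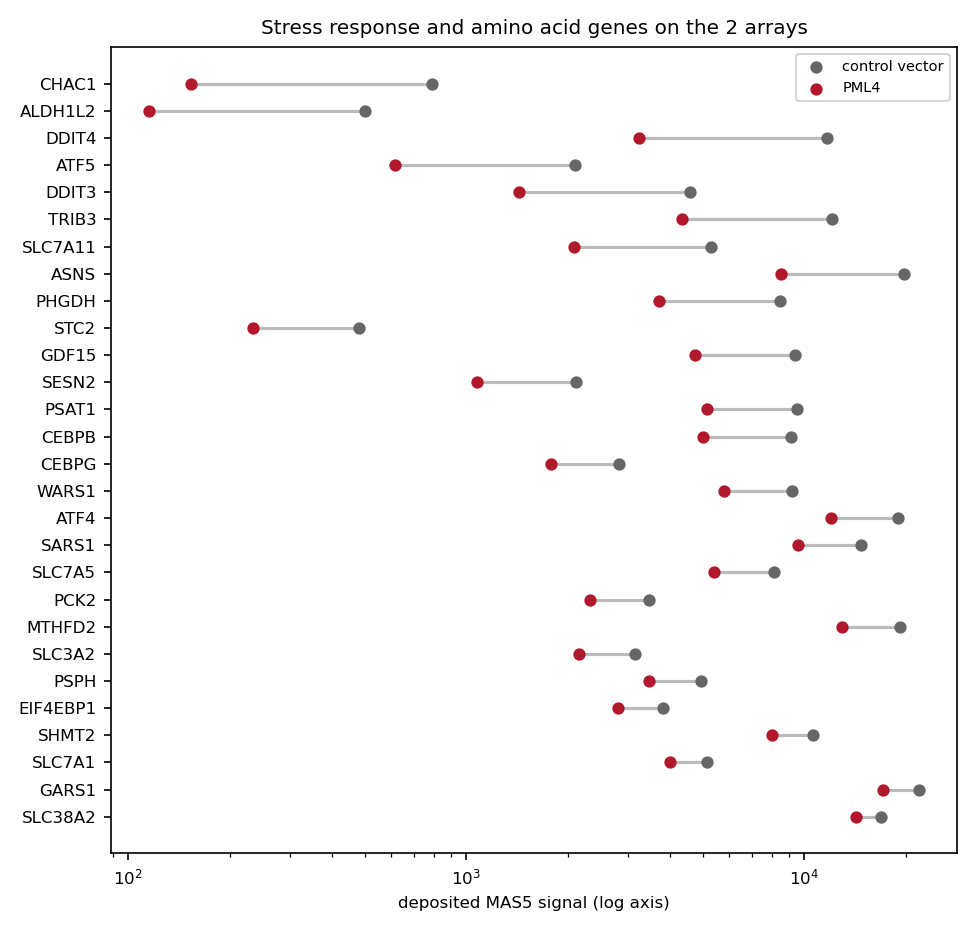
Deposited MAS5 signal (log axis) of the 28 measured genes of the stress response and amino acid list on the control vector array (grey) and the PML4 array (red), ordered by their difference. Each gene lies lower on the PML4 array, from CHAC1 at 792.3 and 152.8 to SLC38A2 at 16852.8 and 14248.8.

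Erythroid genes did not move as a block. Among hemoglobin genes 5 had a measured probe set of their own, and HBZ was the only call. HBE1, epsilon-globin, was at 18103.9 and 24540.1, a 1.36-fold higher signal, and HBQ1 was at 1378.9 and 1165.0. The list's median was 0.44, above the random range of -0.38 to 0.35, but it was 0.10 and inside the range without a floor. Globin genes are near-identical copies in part, so their signals can hold cross-hybridisation. HBG1, HBG2 and HBA1 were not analysed here, because the table used names them in no probe set with 1 gene. Of 25 heme and iron genes none was called higher and 2 were called lower: ALAS2, the erythroid form of the first enzyme of heme synthesis, was at 272.3 and 106.1, and ABCG2, a transporter, was at least 3.18-fold lower. Of 21 erythroid membrane genes EPOR, the erythropoietin receptor, was the only call, at 760.3 and 364.8, and its 4 probe sets disagreed in direction. None of the 21 measured genes of erythroid maturation was called. The medians of these lists, 0.08 for heme and iron genes, -0.16 for membrane genes and -0.000527 for maturation genes, lay inside their random ranges. The membrane list moved below its range after quantile normalization, at -0.19, after loess centring, at -0.19, and without probe sets ending in _x_at or _s_at, at -0.33.

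Hematopoietic transcription factors were slightly higher as a list. Of 29 measured genes 21 had a higher and 8 a lower signal with PML4. The 2 calls were GFI1, a zinc finger repressor, 2.85-fold higher at 91.3 and 260.1, and LDB1, a cofactor of GATA1 complexes, 2.04-fold higher at 582.8 and 1190.1, with a mean over its probe sets of 0.70 on the log2 scale, under the size of a call. GATA1, the main erythroid transcription factor, was at 2333.2 and 2821.9, and its other probe set was at 1698.8 and 1186.0. KLF1, a regulator of globin genes, was at 3062.8 and 3196.4. The 3 brightest members were MYB at 17016.4 and 21722.5, CBFB at 7787.3 and 9716.7 and LYL1 at 6849.5 and 5534.2. The list's median of 0.24 lay above the random range of -0.12 to 0.16. It lay inside with the floor at the 25th percentile and with the mean of probe sets, and its lowest value was 0.06.

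Markers of other lineages held calls in both directions. The 6 lists together, pooled after their calls were seen, held 12 calls in 60 measured genes, 7 higher and 5 lower, against means of 0.81 higher and 2.47 lower in random lists. None of 10000 random lists held as many higher calls, and 9.4% held as many lower ones. The pooled lists held 11 calls after quantile normalization and 10 after loess centring, against random means of 2.68 and 2.55. With the floor at the 25th percentile they held 31 against 27.4, and 9.05% of random lists held as many higher and 54.86% as many lower calls. Because the pooling followed from the calls, these shares describe them and do not test them. Of 14 megakaryocyte and platelet genes TUBB1, the platelet beta-tubulin, was 2.45-fold higher and F2R, a thrombin receptor, 2.29-fold lower. ITGA2B, the platelet integrin alpha chain, was at 888.4 and 909.4. Of 12 myeloid genes FCER1G, an Fc receptor chain, was at least 2.37-fold higher and CSF3R, the G-CSF receptor, 3.64-fold lower. Of 7 lymphoid genes PRF1 was 3.36-fold, CD3G 2.61-fold and CD3D 2.02-fold higher, the CD3 genes encoding chains of the T cell receptor complex, and CD5 was at least 2.22-fold lower. None of the 10000 random lists held as many higher calls as the 3 lymphoid ones, while the lymphoid median of -0.27 lay inside its range. After quantile normalization and after loess centring the log2 difference of CD3D was 0.97, under the size of a call, which left 2 higher calls. Of 9 stem and progenitor genes CD44, an adhesion receptor, was 2.11-fold higher in 9 of 9 probe sets by direction, though their mean log2 difference was 0.58, under the size of a call. PROCR, the protein C receptor, was 2.06-fold lower. Its log2 difference was -0.80 with the floor at the 75th percentile. Without a floor and under the other scalings it was -0.983 to -0.998, just under the size of a call. KIT, the stem cell factor receptor, was at 3569.1 and 5622.0 and CD99 at 4446.5 and 5082.1. That list's median of 0.19 lay just above its range, and 5 of 9 alternatives put it inside, among them quantile normalization and loess centring, both at 0.16, and the floor at the 25th percentile, at -0.11. Of 10 fibroblast genes SPARC, a matrix protein, was the only call, 2.75-fold lower. FN1 was at 3076.0 and 3177.6 and COL1A1 at 394.2 and 278.6. The fibroblast median of -0.57 lay just below its range of -0.54 to 0.11, and 4 of 8 alternatives put it inside. Of 8 epithelial genes KRT19 was the only call. The medians of the megakaryocyte, myeloid and epithelial lists, -0.19, 0.03 and -0.04, lay inside their ranges, and the myeloid one lay above its range in 3 of 8 alternatives, at 0.12 to 0.14.

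Antigen presentation genes were lower as a list, and calls among interferon genes were mostly lower. Of 18 measured genes of MHC class I presentation, 13 had a lower signal, and the median of -0.37 lay below the random range of -0.19 to 0.20. ERAP2, a peptidase that trims antigenic peptides, was the only call, 3.08-fold lower. The 3 brightest members were B2M at 27579.2 and 27907.8, CANX at 10493.8 and 9634.9 and CALR at 3537.8 and 2646.9. HLA genes are close paralogs and their signals can be shared. With the floor at the 75th percentile the median was -0.10 and lay inside the range. Of 35 interferon response genes 5 were called lower and none higher. TRIM22, an antiviral ubiquitin ligase, was 4.86-fold lower, HERC5 2.36-fold, GBP2 2.30-fold and LGALS3BP 2.27-fold, and OAS3, named after its value was seen, was at 356.2 and 169.4. As many lower calls occurred in 3.48% of random lists, and the median of -0.17 lay inside its range. Of 9 alternatives 3 gave a higher call: quantile normalization and loess centring each gave 3 lower and 1 higher, and the floor at the 25th percentile gave 8 and 2. The other 6 gave no higher call and between 1 and 5 lower ones.

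Mitotic genes, genes of ribosome biogenesis and lipid synthesis genes had small positive medians without calls. Of 38 mitotic genes 28 had a higher signal and none was called, with a median of 0.21 against a random range of -0.07 to 0.15. CDK1, the mitotic kinase, was at 13196.7 and 14427.9, MAD2L1 at 11283.8 and 8781.9 and PRC1 at 9184.3 and 9662.1. Of 40 DNA replication genes none was called, and the median of 0.01 lay inside its range. Of 25 genes of ribosome biogenesis and MYC targets 19 had a higher signal, with a median of 0.22 against -0.15 to 0.15. The brightest were NPM1 at 31527.6 and 27770.8, LDHA at 16118.5 and 17525.6 and NCL at 16882.3 and 14793.6. Of 23 genes of cholesterol and fatty acid synthesis 17 had a higher signal, with a median of 0.27 against -0.15 to 0.19. SQLE, an enzyme of sterol synthesis, was 1.75-fold higher at 7660.4 and 13388.9, ACLY 1.43-fold and SCD 1.15-fold. These 3 medians stayed above their ranges under all 9 alternatives, of which centring could not change their side.

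Genes of cytosolic ribosomal proteins were lower in 29 of 29 measured members as deposited, and none was called. RPS23 was at 49251.1 and 40760.5, RPL7 at 46981.6 and 41501.8 and RPS16 at 46992.9 and 40812.9. Their median of -0.20 lay below the random range of -0.13 to 0.08. After quantile normalization it was -0.03 and lay inside the range. Of 15 histone genes H2BC4 was the only call, 2.18-fold higher, and H2AZ1 was at 23171.3 and 22855.0, H2BC12 at 18914.0 and 25633.9 and H2AZ2 at 10257.6 and 11313.1. The histone median of 0.19 lay above its range of -0.22 to 0.17, and 4 of 9 alternatives put it inside.

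Of the 36 lists, 7 medians lay above and 4 below their random ranges. By chance 1.8 would lie outside if the genes of a list varied like genes drawn at random. Genes of a list move together between any pair of cultures, so the count is not a measure of excess over chance. The medians of the other lists lay inside their random ranges. Of 23 p53 target genes TNFRSF10B, a death receptor, was the only call, 2.01-fold lower. BCL2, the apoptosis inhibitor, was 2.56-fold higher at 113.7 and 291.4, although its 2 probe sets disagreed in direction. CDKN1C, a cell cycle inhibitor, was 2.47-fold lower, although the mean over its probe sets, -0.78 on the log2 scale, was under the size of a call. Of 19 inflammatory and NF-kB genes 3 were called lower, CXCL8 by at least 6.35-fold, TNFAIP3, an NF-kB inhibitor, by 3.08-fold and the cytokine IL6 by 2.14-fold. Of 28 immediate early genes ATF3 was 2.43-fold, KLF10 2.08-fold and ZFP36 2.06-fold lower and SRF 2.02-fold higher, the last with discordant probe sets. The log2 difference of ATF3 was -0.80 with the mean of probe sets, under the size of a call. That of ZFP36 was -0.973 after quantile normalization and -0.982 after loess centring, also under it. SOCS3, a feedback inhibitor of cytokine signalling, was 2.45-fold lower and, with EPOR, made up the 2 calls among 21 JAK-STAT5 and BCR-ABL genes. PKM, pyruvate kinase, was 2.21-fold higher, with a mean over probe sets of 0.90 on the log2 scale, and VEGFA lower among 29 genes of glycolysis and hypoxia. ME1 was 2.02-fold lower and, with SLC7A11, made up the calls among 21 antioxidant genes. ULK1, the autophagy kinase, was 2.13-fold lower, and SSX1 2.42-fold lower among cancer testis genes. No gene was called in the lists for heat shock and unfolded proteins, TGF-beta and BMP response, oxidative phosphorylation, chromatin silencing or housekeeping, whose medians were -0.07, -0.03, -0.03, 0.11 and 0.06. The medians were -0.00382 for p53 targets, 0.12 for apoptosis regulators, -0.03 for cyclins and cell cycle inhibitors, -0.27 for inflammatory genes, 0.00179 for immediate early genes, 0.04 for JAK-STAT5 and BCR-ABL targets, 0.04 for glycolysis and hypoxia, -0.08 for antioxidant genes, -0.10 for autophagy and lysosome and -0.02 for cancer testis genes. The heat shock and unfolded protein list lay below its range at -0.18 with the mean of probe sets, and the cancer testis list above it at 0.28 with the floor at the 75th percentile.

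**Figure D4:**
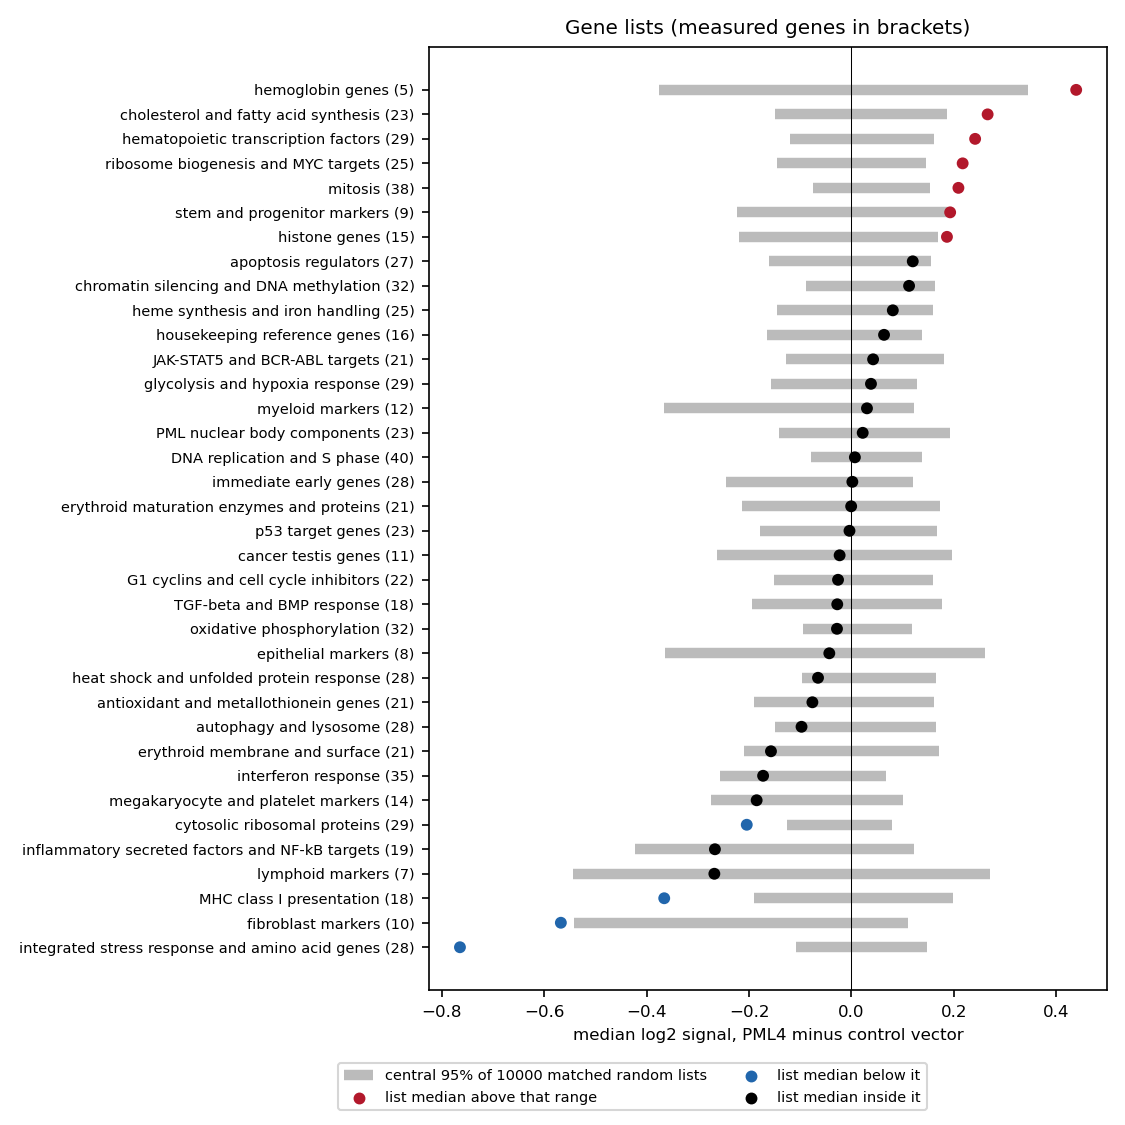
Median log2 difference, PML4 minus control vector (horizontal axis), of the 36 gene lists (points), with the number of measured genes in brackets, and the central 95% of 10000 random lists matched on size and signal (grey bars). The stress response and amino acid list lies farthest from its bar at -0.76, 7 lists lie above their bars and 4 below.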

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

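Control probe sets for ribosomal RNA, which the gene counts leave out, differed between the arrays in both directions. The 5' probe set of 18S rRNA read 5079.3 on the control array and 9084.7 on the PML4 array, and its middle probe set read 4203.3 and 6429.1. The 5' probe set of 28S rRNA read 15061.6 and 20311.5, its middle probe set 5419.1 and 4669.4, and its 3' probe set 28.7 and 13.4. The 3' probe set of 18S rRNA was at 11142.4 and 10369.0, so the 3' to 5' ratio was 2.19 on the control array and 1.14 on the PML4 array. Oligo-dT priming is not meant to copy these RNAs, and no explanation was tested.

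Probe sets without a single named gene also held differences. Of 4642 such probe sets above the floor on both arrays, 57 were at least 2-fold higher with PML4 and 160 at least 2-fold lower, that is 1.23% and 3.45%. Among 20577 probe sets with 1 named gene the shares were 1.19% and 2.59%.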

How the results depend on the processing

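No paired analysis was possible because each group has 1 array. With 1 array per group no library could be left out either. The floor moves the count by construction, since it decides which dim genes enter, and so does the size of a call; the cause of the other shifts was not tested. The numbers of genes 2-fold higher and of genes 2-fold lower were 667 and 2000 with the floor at the 25th percentile, 50 and 63 at the 75th, and 266 and 910 without a floor, on log2 of the signal plus 32. Calls at 1.5-fold gave 715 and 1487, and calls at 3-fold gave 27 and 59. Loess centring gave 265 lower genes, of which 257 were among the 402. Centring on the median, which shifted every gene by 0.05, gave 184 and 341. Of 319 list medians under alternatives, 315 kept within 0.29 of the reported value without reversing. A change of sign counted as reversing only for lists that stood apart. The 0.29 is a spread between single probe sets and is wide for list medians, so keeping within it says little. Ribosomal proteins at -0.03 after quantile normalization and MHC class I genes at -0.10 with the floor at the 75th percentile kept within it but entered their random ranges. Hemoglobin genes moved to 0.10 without a floor and cancer testis genes to 0.28 with the floor at the 75th percentile. Stem and progenitor markers reversed, to -0.11 with the floor at the 25th percentile and -0.093 without one, where 17 and 19 genes of the list entered instead of 9. The lists for mitosis, ribosome biogenesis, lipid synthesis and the stress response kept their side of the random range under all 9 alternatives, of which centring could not change it. Of the 25 lists inside their range, 4 left it under some alternative. For PML, the floor at the 75th percentile gave -0.996 for 206503_x_at, 0.59 for 210362_x_at, 1.58 for 211013_x_at and 0.00 for 209640_at, 211012_s_at, 211588_s_at and 239582_at, which were then all at the floor. Without a floor 210362_x_at was 2.49 and 211588_s_at -0.90. With the floor at the 25th percentile 211588_s_at was -1.37 and 239582_at -0.86. Over all human probe sets with a pseudocount of 32 the Pearson r was 0.976. Of 766 values of the 102 named genes under alternatives, 710 kept within 0.29 and none of the called genes changed sign. Centring, with its shift of 0.05, could not move a value by 0.29. Of 69 named genes that were called, 69 stayed called with the floor at the 25th percentile, 65 after centring, 60 without a floor, 59 after quantile normalization and 60 after loess centring. For the same probe set a lower floor leaves a difference as it was or enlarges a bound, so it could hardly remove a call. Centring raised every difference by 0.05, so it could only remove lower calls close to 2-fold. With the mean of probe sets 55 stayed called. The other 14 fell under 2-fold, to log2 values of 0.33 for PML, -0.21 for EPOR, 0.51 for SRF, 0.58 for CD44, 0.61 for BCL2, 0.70 for LDB1, 0.73 for IMMP1L, -0.78 for CDKN1C, -0.80 for ATF3, -0.88 for MUC4 and TNFRSF10B, 0.90 for PKM and 0.96 and -0.96 for CAVIN1 and GBP2. With the floor at the 75th percentile 33 stayed called, 15 fell under 2-fold and 21 were no longer measured. Without probe sets ending in _x_at or _s_at 51 stayed called, 14 had no value, and PML, ATF3, IMMP1L and ASNS fell under 2-fold, to 0.23, -0.69, 0.44 and -0.92. The floor limits what dim genes can show.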

Other observations

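The tests on endoplasmic reticulum genes, on T and NK cell transcripts, on mast cell, basophil and eosinophil genes, on differences between the cultures and on the position of PML probes were chosen after the results, or part of the values they use, had been seen. Genes in the next 2 paragraphs other than SLC18A2 and KIT were chosen after their values were seen.

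Several genes of mast cells, basophils and eosinophils were among the larger differences. PRG2, eosinophil major basic protein, was 4.62-fold higher with PML4 at 576.4 and 2660.4. IL1RL1, the interleukin-33 receptor, was 3.30-fold higher in 3 of 3 probe sets by direction, and HDC, histidine decarboxylase, 2.86-fold. SLC18A2, at least 8.41-fold higher, loads histamine into granules, and RAB27B, a regulator of granule release, was 4.31-fold higher. SELPLG, the P-selectin ligand, was 6.09-fold higher and HPGD, a prostaglandin-degrading enzyme, 3.72-fold. With the mean of probe sets the log2 differences were 1.21 for IL1RL1, 1.39 for RAB27B, 1.88 for SELPLG and 2.22 for SLC18A2, and with the floor at the 75th percentile that of SLC18A2 was 0.39, and HDC, IL1RL1 and HPGD were no longer measured. One hypothesis is a shared shift of this lineage's genes, tested on 30 others written down after the genes above, and ALOX5 among the 30, had been seen. Of these 13 were measured, with a median of 0.32 against a random range of -0.28 to 0.17, and 9 were higher, such as ENPP3 at 689.4 and 975.5 and KIT at 3569.1 and 5622.0. None of the 13 was 2-fold higher, ALOX5 was 3.16-fold lower, though at -0.88 on the log2 scale, under the size of a call, with the mean of its probe sets and at -0.54 with the floor at the 75th percentile, and 4 of 8 alternatives put the median inside the range, with values down to -0.09. KIT and GATA2 also belong to lists fixed earlier. Without these and ALOX5, a choice made later still, the other 10 had a median of 0.36 against a range of -0.36 to 0.16, and 3 of 8 alternatives, those that move the floor or leave it out, put it inside. The hypothesis stays open, since these values depend on the floor and the list was written after the pattern was seen.

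Some single genes outside the fixed lists were lower with PML4. They were picked for the size of their difference, and no gene set was tested on them. ASS1, argininosuccinate synthase, was 4.88-fold lower at 2257.0 and 462.3, ARG2, mitochondrial arginase, 3.74-fold and INHBE, an inhibin subunit, 4.94-fold. The hormone ERFE was 3.24-fold lower. S100P was 7.98-fold lower and PAPPA 6.90-fold, in 6 of 6 probe sets by direction. The log2 difference of PAPPA, -2.79, was -1.50 with the mean of probe sets and -1.71 without probe sets ending in _x_at or _s_at, and that of ARG2, -1.90, was -1.27 without these. With the floor at the 75th percentile S100P was at -0.79 and PAPPA at -0.24.

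The first pattern is the lower signal of stress response and amino acid genes. Scaling is argued against as its cause, since the median was -0.79 both after quantile normalization and after loess centring, below the random range each time. Centring on the median gave -0.72, but it could not change the side of the list. Lower output of the transcription factor ATF4 is a candidate explanation: cytosolic aminoacyl-tRNA synthetases outside the list, which it is known to induce, had a median of -0.41 over 14 genes, below a random range of -0.17 to 0.17, and the mitochondrial ones had 0.08 over 15 genes, inside theirs. Lower endoplasmic reticulum stress stays open: the whole unfolded protein list had a median of -0.07, inside its random range, whereas its 15 endoplasmic reticulum members, picked after their values were seen, had -0.28, below theirs but nearer to 0 than the stress list, and without probe sets ending in _x_at or _s_at they had -0.19, inside their range. A difference between the 2 cultures unrelated to PML4, such as medium or cell density, cannot be told apart from an effect of PML4, because there is 1 array per group.

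The second pattern is the higher signal of PRF1, CD3D and CD3G. T or NK cells in the PML4 culture are argued against, because 23 other abundant transcripts of such cells, 10 of them also in the lymphoid list, whose calls had been seen, had a median signal of 29.2 on the PML4 array, none was 2-fold higher, and 16 were at or under the floor on both arrays. The brightest of the 23 were CD52 at 2695.3 and 3818.8 and CD69 at 4701.5 and 3392.4, and CD3E was at 105.9 and 55.3. PRF1 reached 11617.0 on the PML4 array, where NKG7, GNLY and GZMB were at 24.1, 33.8 and 9.1. Some dimmer genes linked to such cells go the other way, all but TRDV3 chosen after their values were seen: IKZF3 was at 88.6 and 346.7, 3.91-fold higher, with a log2 difference of 1.97 that was 1.10 with the mean of probe sets, IL18RAP at 103.7 and 295.4, 2.85-fold, SH2D1B at 48.7 and 202.2, at least 2.79-fold, and TRDV3 at 14.2 and 491.3, at least 6.79-fold. With the floor at the 75th percentile TRDV3 had a log2 difference of 0.08 and the other 3 were no longer measured. The cause of these differences stays open. Scaling is argued against too, since the lowest of the 3 differences under 3 other scalings was 0.97. An effect of PML4 or a difference between the cultures stays open, with 1 array per group, as does cross-hybridisation, which was not tested.

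The third pattern is the opposite direction of PML probe sets. Ordinary spread between probe sets of 1 gene is argued against, since the range of 5.40 across the 7 PML probe sets above the floor on both arrays was the widest of 2446 genes with at least 3 such probe sets, a share of 0.0409%, and the next widest was 2.66. Probe sets that read sequence the transduced cDNA lacks would miss the transgene. That could keep their difference near 0, but it would not by itself give a value such as -2.57 for 206503_x_at. Which probe sets read such sequence cannot be decided without the positions of the probes. A lower level of some endogenous PML transcripts stays open as well. Every PML probe set that differed by at least 2-fold ends in _x_at, and cross-hybridisation, which was not tested, stays open too.

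A copy number difference between the cultures was tested, as a hypothesis, on 12507 genes in runs of 40 neighbouring genes. The most extreme run, from CTCF to PDPR, had a mean centred difference of 0.27, and 730 of 1000 shuffled gene orders held a run as extreme. A difference of that length was not seen, and shorter or smaller ones were not resolved.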
